A study of Mus musculus with 6 samples.

How the data were processed

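RNA was measured by sequencing in 6 libraries of E14 cells, a mouse embryonic stem cell line. All libraries came from cells treated for 4 days with retinoic acid, 3 of wild-type cells and 3 of cells with an enhancer cluster knocked out. The series' design text calls the 3 libraries of each group biological replicates. The number of knockout clones and the position of the deletion were not given in the sources used here.

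The authors deposited 1 table per library, holding whole-number read counts per Ensembl gene, not normalised. Per the submitters' processing notes, the tools were HISAT2 2.1.0, an aligner, HTSeq 0.9.1, a read counter, and DESeq2 1.18.1, and the genome build was mm10. The annotation release, the read layout and the strand setting were not given in the sources used here. Each deposited count table ends with 5 tallies of reads that HTSeq gave to no gene, and these stayed out of library sizes and tests. Reads that HTSeq tallied under no feature made up 42.3 to 43.5% of each library, more than the 36.0 to 38.4% assigned to genes. As the strand setting was not given, they may include reads over annotated exons that were read as lying on the other strand. Reads aligned to more than 1 place made up 13.8 to 15.0%, ambiguous reads 0.745 to 0.902%, reads of low alignment quality 2.86 to 3.53% and unaligned reads 1.23 to 2.31%.

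Gene symbols, positions, lengths and exon overlaps were taken from the GENCODE M21 annotation of GRCm38, the same build as mm10. Of 52636 gene identifiers in the files, 52403 matched a symbol, and the other 233 held 0.0472% of the counts. Whether the counts separate strands was checked on 32 single-exon genes lying inside an exon of a gene on the other strand. Their median read density was 0.830 of that of the host gene's exons, and 23 of the 32 were at 0.2 or more. The counts were therefore treated as not separating strands, so a gene and its antisense partner cannot be told apart where their exons overlap.

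Counts were tested with edgeR 4.0.16 in R 4.3.3 on the 6 libraries together, knockout against wild type, with no covariate. Genes were kept by filterByExpr with a minimum count of 10, which left 15816 of 52636, and libraries were scaled by TMM. Quasi-likelihood F tests were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are knockout over wild type, and the SE was derived from the fold change and its F statistic. CPM values are counts scaled to library size after TMM, given as mean ± SD over 3 libraries. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound for counting error only.

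Gene lists (33 lists, 522 entries) were fixed before the data were examined. They cover the Hox clusters and their neighbours, the retinoic acid pathway, pluripotency, neural types, other germ layers, signalling pathways, imprinted and germline genes, and signs of handling, stress and RNA quality. Each list was tested against all other tested genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, were run beside it. The HoxB list, named in the series title, was read by its unadjusted p. Genes within 1 Mb of HoxB and genes of each chromosome were tested in the same way.

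Named genes followed a rule fixed before the data were examined. It takes every tested HoxB coding gene and the 10 largest rises and 10 largest falls past the threshold with all 3 knockout values on one side of the wild-type values. Those 20 also needed a mean CPM of at least 5 in the higher group and a symbol that is not a predicted-gene name. From each other list it takes up to 4 members with the smallest adjusted p past the threshold. Other list members are named by value alone, and genes chosen after their values were seen are marked so. Some genes that the rule takes are not reported here.

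Counts of changed genes and named genes were recomputed with DESeq2 1.42.0 and limma-voom, and these and the list tests with RLE and upper-quartile scaling and with no filter beyond 1 count in total. Other alternatives were a CPM of at least 1 in 3 libraries, the replicate number as a block, removal of a trend on GC content or on gene length, and each library left out in turn. Further alternatives, chosen after seeing the data, left out ribosomal RNA locus and mitochondrial genes, the 20 most abundant genes, or genes overlapping the other strand. The tests by position were repeated only with an estimated correlation and with each library left out, and around HoxB also with windows of 500 kb and 2 Mb.

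The procedure was tested on simulated counts for the 15816 genes in the same 3 against 3 layout, with 50 genes changed at each fold size. The edgeR test recovered 68% of genes changed 1.5-fold, 76% at 2-fold, 94% at 4-fold and 98% at 8-fold. Of 183 calls, 15 were false (8.20%), above the nominal 5%. The simulation changed a far smaller share of genes than the 68.6% that changed in the data, so these shares may not hold there. Depth was 7780368 to 9472916 gene counts per library, and counting intervals and floors cover counting error only, since the reads carried no stated molecular identifiers.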

Results

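Gene expression was measured in mouse E14 embryonic stem cells after 4 days of differentiation with retinoic acid, a vitamin A derivative that drives stem cells towards neural fates and turns on Hox genes. The stem cells had been grown with LIF and inhibitors of MEK and GSK3, which were withdrawn for the differentiation. Retinoic acid was used at 5 µM, a unit the labels write as µm. There were 3 wild-type libraries and 3 libraries of cells lacking an enhancer cluster that the series title links to HoxB activation and neural progenitor formation. Gene counts were 8523464, 9472916 and 8208615 in wild-type replicates 1 to 3, and 7780368, 7965682 and 8521902 in knockout replicates 1 to 3.

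Libraries of 1 group resembled each other more than those of the other group, with Pearson correlations across genes of log2 CPM of 0.987 to 0.989 within groups and 0.918 to 0.920 between them. No replicate pair matched within sampling noise. The chi-square per degree of freedom was 1.94 to 2.13 for the wild-type pairs, 2.51 for knockout replicates 2 and 3, and 6.64 and 8.002 for the pairs with knockout replicate 1. In that library, genes over ribosomal RNA repeats (Gm42418, Gm26917, CT010467.1, Gm23935 and Lars2, chosen after their values were seen) held 1.04% of counts, against 0.0726 to 0.118% in the other 5 libraries. Mitochondrially encoded genes held 1.67 to 1.73% of counts in wild-type libraries and 2.58 to 2.89% in knockout libraries. These genes did not rise alike, and of 12 tested in the fixed list 7 rose and 1 fell. The gene mt-Co1 went from 5960.6 ± 109.4 to 14715 ± 939.6 CPM. In contrast mt-Cytb, chosen after its value was seen, went from 2971.3 ± 29.0 to 2699.9 ± 143.7 CPM.

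The first comparison asks whether HoxB genes were lower without the enhancer cluster. The cluster of homeobox genes, which set position along the body axis, lies on chromosome 11 from 96194316 to 96368256 (GRCm38). Of its 10 coding genes, 6 fell in the knockout, 0 rose and 4 did not pass the test. Hoxb9 (ENSMUSG00000020875, 96271457 to 96276595) fell by 0.95 on the log2 scale (SE 0.082, n = 3 per group), from 51.9 ± 1.69 to 26.8 ± 0.536 CPM. Hoxb2 (ENSMUSG00000075588) fell by 0.85 (SE 0.080), from 53.1 ± 1.10 to 29.5 ± 1.33 CPM, and Hoxb3 fell by 0.79 (SE 0.12), from 21.4 ± 0.825 to 12.4 ± 0.890 CPM. Hoxb5 fell by 0.99 (SE 0.22), Hoxb8 by 0.68 (SE 0.18) and Hoxb1 by 0.33 (SE 0.10). The log2 fold changes were -0.14 for Hoxb4 (SE 0.13), -0.36 for Hoxb6 (SE 0.24), 0.19 for Hoxb7 (SE 0.22) and -0.06 for Hoxb13 (SE 0.29). The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.14e-10 for Hoxb9, 6.47e-10 for Hoxb2 and 0.00593 for Hoxb1.

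In every knockout library, these 6 genes lay below every wild-type library. Such separation of the groups, in either direction, was seen in 70.9% of all tested genes, so it is not particular to HoxB. Of all 15816 tested genes, 68.6% changed, 5463 higher and 5385 lower. Hoxb9, for example, stood at 51.6, 50.4 and 53.8 CPM in wild type and at 27.4, 26.5 and 26.6 CPM in the knockout. Adjusted over the list alone, the counts were also 6 lower and 0 higher, and at an unadjusted p under 0.05 no HoxB gene was higher. Because the deletion's position is not in the labels, these counts describe the cluster named in the title and do not check the deletion itself.

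**Figure D1:**
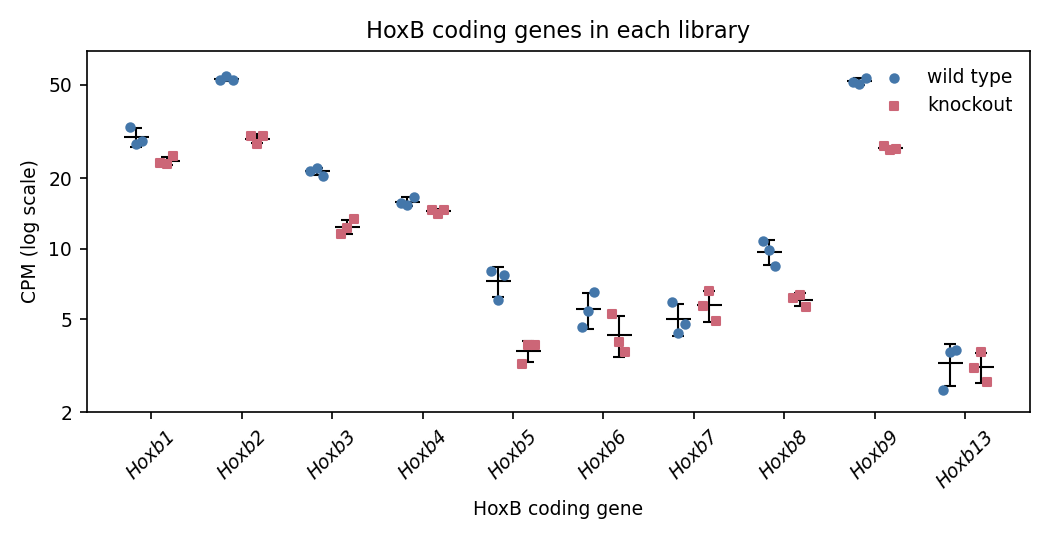
CPM of each HoxB coding gene (log axis) in each of the 3 wild-type (circles) and 3 knockout (squares) libraries, with the mean (bar) and SD (whiskers) of each group. The knockout points of Hoxb1, Hoxb2, Hoxb3, Hoxb5, Hoxb8 and Hoxb9 lie below all wild-type points, as do those of Hoxb4, which like Hoxb6, Hoxb7 and Hoxb13 did not pass the test.

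As a list, the HoxB genes had a median log2 fold change of -0.52, and camera, which draws on all tested genes, gave a p of 0.0492, or 0.162 adjusted over the 33 lists. The p was 0.109 with an estimated correlation. It lay above 0.05 without knockout replicate 1 (0.137), knockout replicate 2 (0.0722), knockout replicate 3 (0.058) or wild-type replicate 3 (0.0522), while 6 HoxB genes were lower in each of these. Exons of Hoxb3os on the other strand cover 52.9% of the exon length of Hoxb3 and 27.3% of that of Hoxb2, and Hoxb5os covers 3.59% of Hoxb5, so reads of these pairs are not separated.

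HoxA and HoxC genes moved both ways. Of 10 HoxA genes tested, 2 rose and 5 fell, among them Hoxa3 (log2 fold change -1.14, SE 0.11), Hoxa5 (-0.97, SE 0.096) and Hoxa7 (-1.29, SE 0.16). Exons of Hoxa3 and Hoxa7 are partly overlapped by genes on the other strand. Of 7 HoxC genes, 2 rose and 2 fell, with Hoxc4 at 1.08 (SE 0.15) and Hoxc9 at -1.36 (SE 0.17). Of 4 HoxD genes tested, 2 fell, Hoxd8 by 1.17 (SE 0.22) and Hoxd13 by 0.67 (SE 0.18). Hoxc6, at 0.70, did not pass without wild-type replicate 2 or 3 or knockout replicate 1 or 2 (adjusted p by edgeR 0.06305 to 0.0902), nor did Hoxc13, at -0.48, without knockout replicate 2 (0.0585). Adjusted over the list alone, the counts of these 3 lists were the same. Over the 21 HoxA, HoxC and HoxD genes, 4 rose and 9 fell and the median was -0.40 (camera p of 0.178). The HoxB median minus that of the other clusters was -0.12 (95% bootstrap interval -0.58 to 0.35 over genes, two-sided permutation p = 0.624), so a difference between HoxB and the other clusters was not detected.

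Noncoding genes inside the Hox clusters included 1 that rose and 4 that fell among 8 tested, and adjusted over the list alone the counts were the same. Mir196a-1, the locus of a microRNA between Hoxb9 and Hoxb13, had 29, 48 and 26 counts in wild type and 2, 3 and 6 in the knockout (log2 fold change -3.08, SE 0.43). Hoxb3os fell by 0.69 (SE 0.071) and Halr1, beside the HoxA cluster, by 1.47 (SE 0.15).

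The next comparison asks whether genes near HoxB moved with it. Of 46 other genes tested within 1 Mb, 13 rose, 21 fell and the median log2 fold change was -0.17, which camera did not set apart from other genes (p of 0.1996, and of 0.315 with an estimated correlation). Within 500 kb the median of 20 such genes was lower, at -0.62, with 5 that rose and 10 that fell (p of 0.134, and of 0.334 with an estimated correlation). The 1 Mb median was -0.29 without wild-type replicate 3 and -0.30 without knockout replicate 3. In the fixed list of neighbours, 7 of 23 tested genes rose and 12 fell (7 and 13 adjusted over the list alone). Igf2bp1, an RNA-binding protein gene at 95957163 to 96005940, fell by 0.82 (SE 0.040) and Atp5g1, a subunit of ATP synthase, by 1.25 (SE 0.082). Kpnb1, encoding importin beta, fell by 0.48 (SE 0.029), while B4galnt2 rose by 1.74 (SE 0.11). Gm53, a noncoding gene between Hoxb9 and Hoxb13 that was chosen after its value was seen, was at -1.54 (SE 0.12). Next to Hoxb13, every tested gene from Igf2bp1 to Ttll6 (95957163 to 96165451) lay below 0. They ranged from -0.28 for Gm29202, which did not pass the test, to -2.05 (SE 0.18) for Calcoco2. This stretch was chosen after its values were seen and was not tested as a set.

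**Figure D2:**
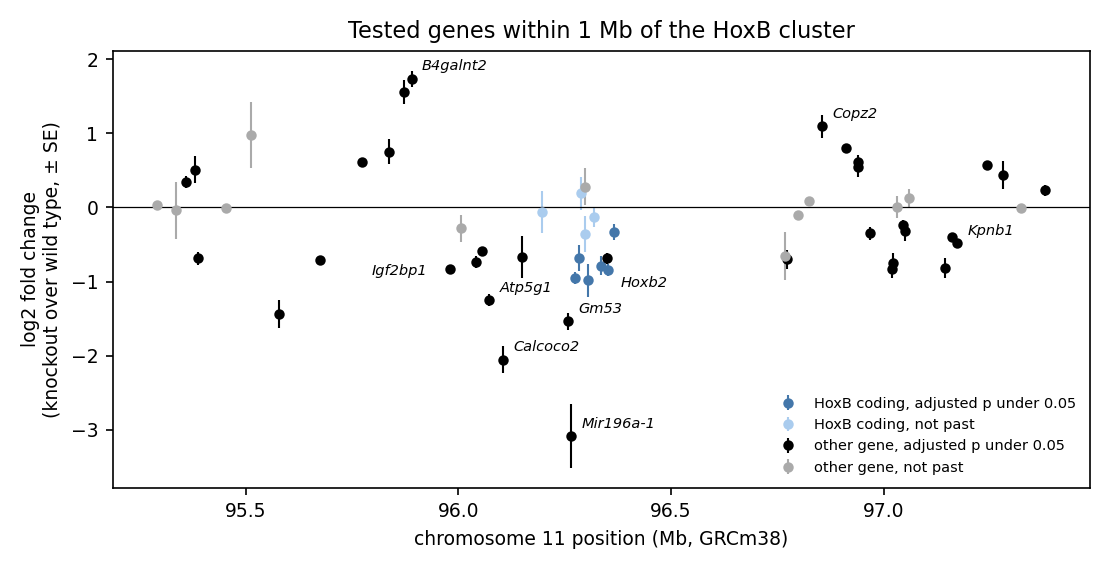
Log2 fold change of knockout over wild type (y axis, bars show the SE) for each tested gene within 1 Mb of HoxB by its midpoint on chromosome 11 in Mb (x axis). HoxB coding genes are in blue, and genes on both sides lie above and below 0, from Mir196a-1 at -3.08 to B4galnt2 at 1.74.

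Across chromosomes, no set of genes stood apart. Of 21 chromosomes, 0 passed camera after Benjamini-Hochberg adjustment and 1, the mitochondrial genome, had an unadjusted p under 0.05 (p of 0.0268). With an estimated correlation, 0 passed and 0 had an unadjusted p under 0.05. The largest median among nuclear chromosomes was 0.093, for chromosome 13. Without knockout replicate 1, 1 chromosome passed.

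Over all genes, 10848 of 15816 tested (68.6%) changed, 5463 higher and 5385 lower in the knockout. An absolute log2 fold change of at least 1 was seen in 3323 of them, 1826 higher and 1497 lower, and the median absolute log2 fold change of all tested genes was 0.49. In 11210 genes (70.9%) the 3 knockout values did not overlap the 3 wild-type values, against 10% by chance. The biological coefficient of variation was 6.08%. The balance of rises and falls depends on the scaling. The median log2 fold change of all tested genes was 0.0091 with TMM and 0.046 with upper-quartile scaling, which gave 5769 higher and 5104 lower. Counts scaled to library size do not show a change in total RNA per cell.

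Among the largest rises, Depp1, a gene regulated by FOXO factors, had 0 counts in the wild-type libraries and 177, 157 and 157 in the knockout, at least 175-fold higher against a floor of 3 counts over the group. Enpep, encoding glutamyl aminopeptidase, rose by 5.98 (SE 0.34), from 0.192 ± 0.0660 to 13.0 ± 2.11 CPM. Apoa1, encoding the main apolipoprotein of HDL, rose by 3.94 (SE 0.29), and Selenop, a secreted selenium carrier, by 3.64 (SE 0.19). Pygl, the liver form of glycogen phosphorylase, rose by 3.46 (SE 0.17). The others of these 10 were Oprk1, Pramel7, Hist3h2ba, Rassf6 and Slc28a1, with log2 fold changes of 4.04, 3.87, 3.85, 3.53 and 3.29.

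Among the largest falls, Ccn4, a secreted Wnt-induced matrix protein, fell by 6.31 (SE 0.23), from 30.5 ± 1.04 to 0.368 ± 0.111 CPM. Ptgs2, encoding cyclooxygenase 2, fell by 5.74 (SE 0.19), and Edn1, encoding endothelin 1, fell by 5.03 (SE 0.19). Myc, a growth-promoting transcription factor, fell by 4.38 (SE 0.13), from 68.0 ± 2.70 to 3.26 ± 1.07 CPM. Tubb3, the neuronal beta-tubulin, fell by 4.92 (SE 0.15), and Stmn4, Sp5, Uchl1os and Inka2 were at -5.64, -5.11, -4.64 and -4.33, Uchl1os being antisense to Uchl1. For Myc the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 6.09e-20.

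Groups of genes were followed with the 33 fixed lists, of which few of the genes above are members. Of the 33 lists, 6 passed camera at the preset correlation, 1 upwards and 5 downwards. With an estimated correlation 0 passed (smallest adjusted p = 0.0832), and 6 had an unadjusted p under 0.05. For the 6 lists that passed at the preset 0.01, the estimated correlation was lower, at -0.0858 to -0.0119. A higher correlation between members is therefore not why their p rose. By fry, 29 of 33 lists moved one way on balance. Adjusted over the list alone, the counts of higher and lower members were the same as over all genes for every list but the HoxB neighbours.

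Genes of primitive and definitive endoderm rose as a list. Of 22 tested, 15 rose, 5 fell and the median was 0.94 (camera with Benjamini-Hochberg, adjusted p = 9.89e-05, and adjusted p = 0.0832 with an estimated correlation). The members with the smallest adjusted p encode components of basement membranes, with Lamb1 at 1.73 (SE 0.022), from 875.1 ± 18.7 to 2900.0 ± 42.4 CPM, Lama1 at 1.59 (SE 0.021) and Col4a1 at 1.37 (SE 0.020). Cubn, an endocytic receptor of visceral endoderm, rose by 2.22 (SE 0.034). Among the list's transcription factors of endoderm, chosen after their values were seen, Sox17 fell by 0.65 (SE 0.12) and Foxa2, at 0.03, did not pass the test. Hnf4a rose by 1.37 (SE 0.21), Gata6 by 1.03 (SE 0.045), Gata4 by 0.65 (SE 0.067) and Sox7 by 0.20 (SE 0.059).

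Targets of FGF and ERK signalling fell. Of 12 tested, 11 fell and 0 rose (at an unadjusted p under 0.05 also 0), with a median of -1.34 (camera adjusted p = 2.06e-08, and adjusted p = 0.0832 with an estimated correlation). Dusp6, a phosphatase that turns ERK off and is itself induced by it, fell by 3.19 (SE 0.058), from 220.8 ± 2.39 to 24.2 ± 2.00 CPM. Spry4 fell by 3.35 (SE 0.14) and Etv5 by 1.49 (SE 0.052), and Spred1 fell as well. The 3 knockout libraries with these falls also had the higher mitochondrial shares, 2.58 to 2.89% against 1.67 to 1.73%. Mitochondrial genes did not rise alike, with mt-Co1 at 1.30 and mt-Cytb at -0.14. The same libraries also had 9 of 14 immediate early genes lower, a list that shares Fos and Egr1 with the FGF and ERK list.

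Targets of Wnt signalling also fell, 10 of 11 tested, with 1 that rose and a median of -1.48 (camera adjusted p = 9.89e-05, and adjusted p = 0.0832 with an estimated correlation). Sp5, a transcription factor induced by beta-catenin, fell by 5.11 (SE 0.34) and Lef1 fell by 2.40 (SE 0.16). Ccnd1, encoding cyclin D1, was at -3.78 (SE 0.11) and Notum at -2.47 (SE 0.17). Exons of Ccnd1, Notum and Lef1 are partly overlapped by genes on the other strand. With the genes that overlap the other strand left out, an alternative chosen after seeing the data, the list's adjusted p was 0.0880.

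Fibroblast and extracellular matrix genes fell in 12 of 17 tested and rose in 3, with a median of -0.93 (camera adjusted p = 9.89e-05, and adjusted p = 0.0832 with an estimated correlation). Vim, encoding vimentin, fell by 2.53 (SE 0.036), Col1a1 by 1.71 (SE 0.045) and Fn1, encoding fibronectin, by 0.93 (SE 0.024). Tagln, an actin-binding protein of smooth muscle, was at -3.07 (SE 0.038), with 0.679 of its exon length overlapped by genes on the other strand.

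Immediate early genes, which respond within minutes to stimuli and to handling, fell in 9 of 14 tested and rose in 0 (camera adjusted p = 0.00273, and adjusted p = 0.131 with an estimated correlation). Dusp1 fell by 1.91 (SE 0.081), Fosb by 2.62 (SE 0.18) and Atf3 by 1.35 (SE 0.084). Cholesterol synthesis genes fell in 9 of 15 and rose in 2 (camera adjusted p = 0.0366, and adjusted p = 0.243 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell by 0.75 (SE 0.051). The cholesterol call was also lost with the replicate block (adjusted p = 0.0806) and with genes overlapping the other strand left out (adjusted p = 0.122).

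The other 27 lists, HoxB included, did not pass camera after adjustment over the lists (adjusted p 0.161 to 0.923), while single members changed in each. Retinoic acid pathway genes moved both ways, with 10 rising and 13 falling of 24 (median -0.24). Crabp1, a retinoic acid binding protein, rose by 2.60 (SE 0.13) and Stra8, a gene induced by retinoic acid, by 1.09 (SE 0.041), whereas the receptor gene Rarg fell by 1.47 (SE 0.076). Pluripotency genes rose in 7 and fell in 11 of 22 (median -0.30). Nanog fell by 2.32 (SE 0.054), Nr0b1 by 3.70 (SE 0.17) and Zfp42 by 1.55 (SE 0.063), while Fbxo15 rose by 2.45 (SE 0.10). Formative and primed pluripotency genes rose in 2 and fell in 8 of 12 (median -0.81), with Dnmt3b, a DNA methyltransferase, at -0.56 (SE 0.046).

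The title's second subject, neural progenitors, was followed with 25 listed marker genes, of which only 16 had enough counts to be tested. Of these 16, 4 rose, 5 fell and 7 did not pass the test (median -0.10). Nes, encoding the intermediate filament nestin, fell by 2.78 (SE 0.059), from 231.5 ± 6.84 to 33.6 ± 3.49 CPM. Cdh2, encoding N-cadherin, fell by 1.52 (SE 0.057) and Sox2 by 1.49 (SE 0.076), while Prom1 rose by 0.72 (SE 0.13). Sox1, an early neural marker, was at -0.11 and did not pass. As a list the neural progenitor genes had a camera adjusted p of 0.236. It was 0.0485 with genes overlapping the other strand left out. Of 22 listed neuron genes, only 11 had enough counts to be tested, and of these 2 rose and 5 fell (median -0.25). Gap43, a growth cone protein, was at -1.92 (SE 0.13), Ina, a neuronal filament, at -2.94 (SE 0.24) and Map2 at 1.63 (SE 0.16).

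Regional markers were mixed. Hindbrain and posterior genes rose in 3 and fell in 3 of 7, with Cdx1 at -2.45 (SE 0.16), and forebrain and midbrain genes rose in 4 and fell in 2 of 12, with Otx2 at -1.21 (SE 0.26) and Lmx1b at 0.77 (SE 0.15). Neural crest genes rose in 3 and fell in 3 of 11, with Snai2 at 2.05 (SE 0.18), Ednrb at 2.01 (SE 0.22) and Ets1 at -1.65 (SE 0.072). In these 3 lists the summaries differ in sign: the median, mean and camera direction were 0.13, -0.20 and down for hindbrain, 0.0094, -0.15 and up for forebrain, and -0.038, 0.29 and up for neural crest.

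Markers of other cell types did not rise together with the endoderm genes. Mesoderm genes rose in 4 and fell in 7 of 16 (median -0.37, camera adjusted p 0.236, and 0.0375 with genes overlapping the other strand left out), with Acta2, smooth muscle actin, falling by 3.65 (SE 0.044), from 1015.7 ± 11.7 to 81.0 ± 5.45 CPM, and Pdgfra rising by 1.22 (SE 0.054). Trophoblast genes rose in 2 and fell in 5 of 8 (median -0.37), with Krt7 at -1.94 (SE 0.13) and Hand1 at -0.49 (SE 0.099). Surface ectoderm genes rose in 1 and fell in 3 of 8 (median -0.14), with Krt19 at -0.87 (SE 0.046) and Epcam at 1.04 (SE 0.065).

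Of the signalling lists, Notch genes rose in 3 and fell in 5 of 12, with a median of 0.19, a mean of 0.02 and a downward camera direction. Hey1 rose by 2.23 (SE 0.26) and Hes1 fell by 0.67 (SE 0.084). Hedgehog genes rose in 2 and fell in 5 of 9 (median -0.54), with Gli3 at -1.50 (SE 0.058) and Ptch1 at 0.74 (SE 0.053). BMP genes rose in 1 and fell in 8 of 12 (median -0.49), with Bmp4 at -2.10 (SE 0.11) and Id2 at 0.96 (SE 0.050).

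Cell cycle genes rose in 5 and fell in 11 of 20 (median -0.16). Mcm5 and Pcna, of DNA replication, fell by 1.04 (SE 0.044) and 0.94 (SE 0.047), and Mki67 rose by 0.58 (SE 0.039). Targets of p53 rose in 5 and fell in 8 of 15 (median -0.43), with Cdkn1a at -0.94 (SE 0.048) and Bbc3 at 1.22 (SE 0.071). Glycolysis and hypoxia genes rose in 7 and fell in 6 of 16 (median 0.028), with Pgk1 at 1.30 (SE 0.027) and Hk2 at -0.97 (SE 0.053). Genes of the unfolded protein response rose in 6 and fell in 4 of 12 (median 0.080). Ddit3, the stress transcription factor CHOP, rose by 2.86 (SE 0.049), from 41.2 ± 0.985 to 299.8 ± 7.79 CPM, and Chac1 fell by 1.93 (SE 0.12).

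Imprinted genes rose in 7 and fell in 7 of 19, with a median of -0.030, a mean of 0.0055 and a downward camera direction. Nnat fell by 1.86 (SE 0.066) and H19 by 1.05 (SE 0.054). DNA methylation and germline genes rose in 7 and fell in 3 of 13 (median 0.32), with Dnmt3l at 1.21 (SE 0.043) and Dnmt1 at -0.70 (SE 0.043). Mitochondrially encoded genes rose in 7 and fell in 1 of 12 (median 0.29, camera adjusted p = 0.236). Without knockout replicate 1 their camera adjusted p was 0.0417. The gene mt-Co1 rose by 1.30 (SE 0.024), from 5960.6 ± 109.4 to 14715 ± 939.6 CPM.

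**Figure D3:**
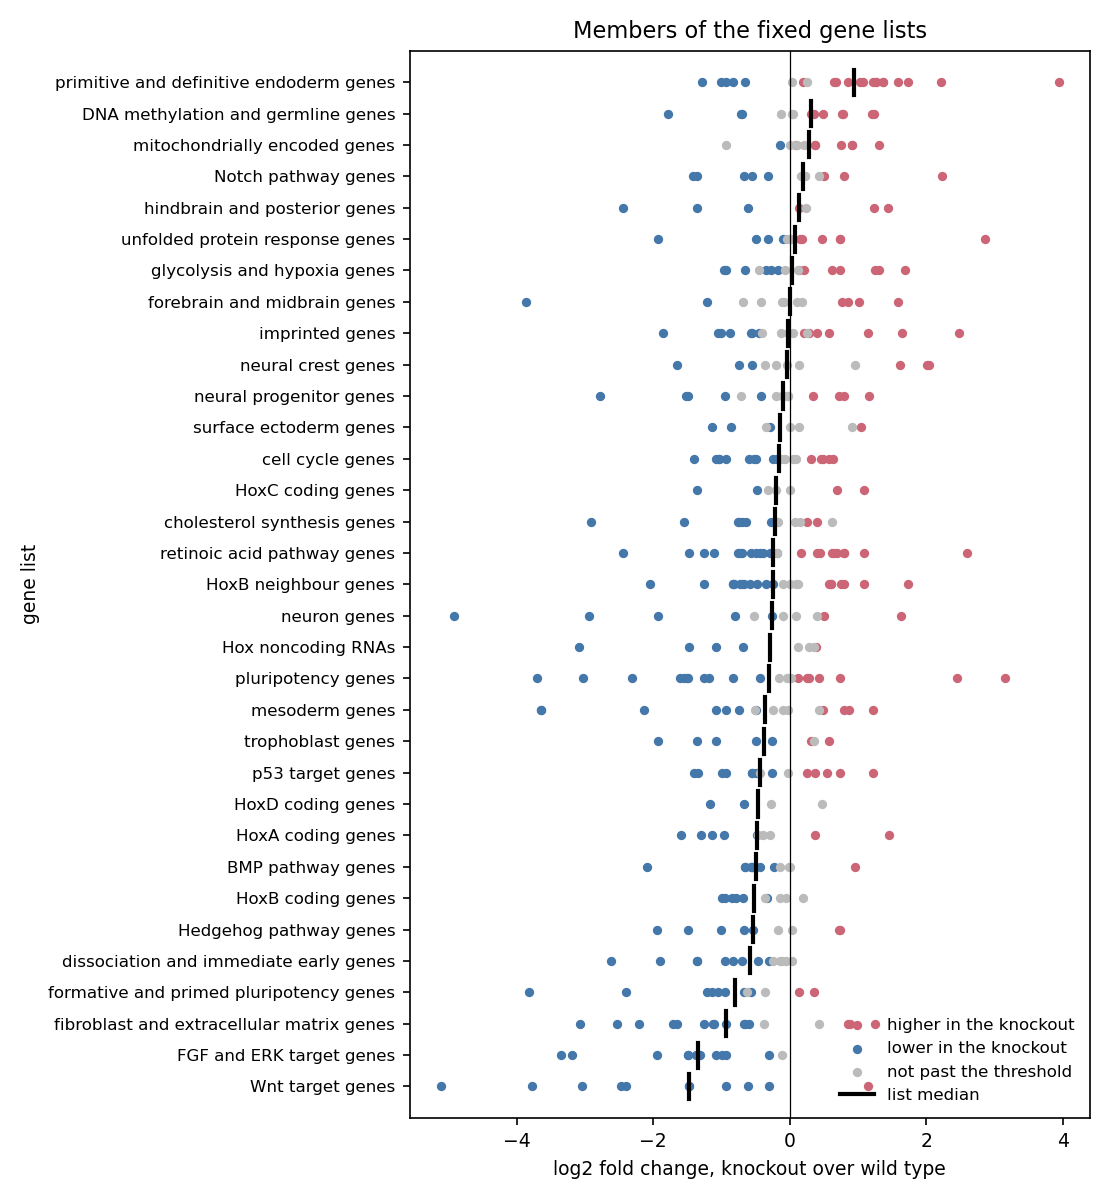
Log2 fold change of knockout over wild type (x axis) of each tested member of the 33 fixed lists (y axis, ordered by median), with members that passed the test in red (higher) or blue (lower), others in grey, and the list median as a black bar. Endoderm genes have the highest median, 0.94, and Wnt target genes the lowest, -1.48.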

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

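The gene lists, the removal of the GC trend, the estimated correlation, the absence of a filter and leaving out single libraries were planned, and the tests of explanations in this part were put together after the results they test had been seen.

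In knockout replicate 1, 2.31% of reads were not aligned, above the highest share in the wild-type libraries. This tally lies outside the gene counts the comparisons use, and its level above the wild-type controls is what drew attention. The same library held the highest share of counts over ribosomal RNA repeats. No biological explanation was tested for it.

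The first pattern is the lower counts of HoxB genes. Reads from genes on the opposite strand are argued against for the HoxB genes with no annotated overlap, of which 3 (Hoxb1, Hoxb8 and Hoxb9) were lower. For Hoxb5 they are argued against too, since its annotated opposite-strand gene Hoxb5os was at 0.28 (SE 0.25) and not lower, while for Hoxb2 and Hoxb3, 2 genes overlapped by the also lower Hoxb3os, reads of opposite-strand genes cannot be told apart from their own. A trend on GC content is argued against as the whole cause, since 6 HoxB genes were lower after it was removed. A fall shared by all Hox clusters stays open (permutation p = 0.624 for HoxB against the other clusters), as does an effect of the deletion on HoxB in particular.

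The second pattern is lower FGF, ERK and Wnt target genes with higher endoderm genes. Knockout replicate 1 with its ribosomal RNA share is argued against, since without it the FGF and ERK list had an adjusted p by camera (limma) of 3.67e-11, within a range of 1.22e-11 to 0.0832 over the alternatives. A lower share of the main cell type that raised the markers of every other type alike is argued against. The median over 6 lists of other cell types was -0.34. The endoderm median lay 1.287 above it (permutation of genes, p = 1e-04), but that list was singled out because it rose, so this p adds no support. A change of cell types that raised endoderm markers alone was not tested and stays open. Carry-over of both stem cell medium inhibitors would raise Wnt targets, whose median was -1.48, while the MEK inhibitor alone was not excluded. A difference in handling stays open as untested, as does a biological effect of the deletion. The mitochondrial share was 2.58 to 2.89% in the knockout against 1.67 to 1.73%. Its rise was not common to all mitochondrial genes, with mt-Co1 at 1.30 and mt-Cytb at -0.14. Of 14 immediate early genes, 9 were lower. The immediate early list shares Fos and Egr1 with the FGF and ERK list, so its fall is not an independent sign of handling.

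The third pattern is that more than 0.5 of the tested genes changed. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split, the only 1 as large, gave 10848 genes and the highest other gave 0 by edgeR (48 to 66 at an unadjusted p under 0.05, 0 to 1 by DESeq2, 0 by limma-voom). Every other split mixes wild-type and knockout libraries on each side, so the group difference counts as spread there. Few calls in those splits were therefore built in, and no conclusion is drawn from them. A few abundant genes taking the counts are argued against, since 10842 genes changed with the 20 most abundant left out. A whole chromosome gained or lost is argued against by the medians of nuclear chromosomes, at most 0.0929 in size. A difference of clone or culture between the groups cannot be told apart from the deletion, since 0 samples carry a label naming a clone, batch or passage.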

How the results depend on the processing

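The alternatives leaving out ribosomal RNA locus and mitochondrial genes, the 20 most abundant genes or genes overlapping the other strand were chosen after seeing the data. The count of changed genes was 3323 (1826 higher, 1497 lower) at an absolute log2 fold change of at least 1 and 7107 (3576 and 3531) with overlapping genes left out, where fewer genes were tested. It was 10359 to 10585 with 1 library left out. The 1 Mb median around HoxB was -0.30 to -0.16 with 1 library left out. HoxB genes lower numbered 3 with overlapping genes left out, since 3 of them were removed, and 6 in the other settings. The HoxB list's p by camera was 0.109 with an estimated correlation, 0.0505 with RLE scaling, 0.075 and 0.0812 with the GC and length trends removed. It was 0.142 without ribosomal RNA locus and mitochondrial genes, 0.0531 without the abundant genes, 0.269 without overlapping genes and 0.0388 to 0.137 with 1 library left out; the cause was not tested. It stayed under 0.05 with no filter (0.00867), upper-quartile scaling (0.0483), the CPM filter (0.0479) and by fry (5.05e-06). Of the other fixed lists, 0 passed with an estimated correlation and 28 by fry, which asks another question. Apart from fry, lists passed that otherwise did not: formative pluripotency (0.0199), BMP and cell cycle genes (0.0315 for both) with no filter, mesoderm genes without ribosomal RNA locus and mitochondrial genes (0.0306) or overlapping genes (0.0375), neural progenitor genes without overlapping genes (0.0485) and mitochondrially encoded genes without knockout replicate 1 (0.0417). Directions reversed, far from the threshold, for neural crest genes by fry (adjusted p 0.460), and for these and retinoic acid pathway genes without ribosomal RNA locus and mitochondrial genes (0.9957 for both). Without overlapping genes they reversed for unfolded protein response genes (0.821) and DNA methylation and germline genes (0.7199). With 1 library left out, adjusted p ranged from 0.717 to 0.996 for the list retinoic acid pathway genes, 0.793 to 0.977 for the list hindbrain and posterior genes and 0.871 to 0.9999 for the list neural crest genes, each with a reversal, and Hoxb13 ranged from -0.23 to 0.040. Chromosomes past the threshold numbered 0 to 1 with 1 library left out. Of values for named genes, 2673 kept direction and side of the threshold, 5 lost the call and 3 reversed. The replicate number as a block gave 10862 changed genes and a HoxB list p by camera of 0.0358. Deviations from the group mean correlated at 0.008 to 0.0466 between libraries of the same number (0 of 3 pairs above 0.1). Between libraries of different numbers they correlated at -0.0454 to -0.0011, and 6 of 6 libraries correlated best with their own number. This is a hint from the data only, and whether the numbers pair samples stays open. At this depth 15816 of 52636 genes had enough counts to be tested, and 68% of simulated 1.5-fold changes were recovered. Other depths, and a share of changed genes as large as in the data, were not simulated.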

Other observations

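All lists and genes in this part were chosen after their values were seen, and the lists were written after the largest changes were known, so their counts describe the chosen genes and test nothing.

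Genes of the actin cytoskeleton and targets of SRF and YAP, which respond to cell shape and adhesion, fell in 20 of 21 tested and rose in 0, with a median log2 fold change of -1.91. Thbs1, a matrix glycoprotein, fell by 3.47, Ccn2, a YAP target, fell by 3.06, Tpm1, a tropomyosin, fell by 2.15 and Flna, an actin crosslinker, fell by 1.91. Amotl2 was at -0.067 and did not pass. Of these genes 2 are also in the fixed lists.

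Visceral endoderm genes rose in 12 of 15 tested, with a median of 1.27, and 6 of them are in the fixed lists. Apoe rose by 1.63, Apob by 1.32 and Rbp4, a retinol carrier, by 1.10. Parietal endoderm genes rose in 10 and fell in 2 of 13, with a median of 0.92, and 7 are in the fixed lists. Srgn, a proteoglycan, rose by 2.04 and Fst, a BMP and activin antagonist, fell by 2.67.

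Some single genes stood apart. Ppp1r10, a phosphatase 1 regulator, fell by 3.92 (SE 0.075), from 140.96 ± 3.95 to 9.29 ± 0.493 CPM. Usp39, a splicing factor, had 120, 161 and 194 counts in wild type and 11, 13 and 4 in the knockout. Its neighbour Rnf181 had 10, 268 and 18 counts in wild type and 15, 22 and 14 in the knockout. Uqcrc1, of respiratory complex III, had 88, 1342 and 15 counts in the knockout libraries. Hnrnpu had 1075, 1277 and 222 counts in wild type and 185, 134 and 832 in the knockout. Among mitochondrial genes, mt-Co1 was at 1.30 and mt-Cytb at -0.14.

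Xist, the noncoding RNA of X inactivation, was at 22.1 ± 1.52 CPM in wild type and 51.4 ± 4.66 in the knockout. Because the counts were treated as not separating strands, these values would include reads of any overlapping gene on the other strand. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 counts and Kdm5d had 1 count over all libraries, at or under the floor of 3 counts.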
